A study of Oryza sativa Indica Group with 8 samples.

How the data were processed

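Total RNA from roots was labelled from 2 ug per sample, hybridised to an Affymetrix rice genome array and processed with Affymetrix Expression Console 3.0 and RMA, per the labels. The deposited values are RMA signals on a log2 scale, background-corrected and quantile-normalised by the authors; the medians of the 8 arrays lay between 5.29 and 5.35. The table held 57381 probe sets; the 123 control probe sets were left out of the tests and used as quality measures, and 57258 were tested. Depth has no meaning for these arrays; their number, 2 per group, limits the precision. The raw scans were not used here.

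The 8 arrays formed 4 groups of 2, taken from the labels: IR20 control, IR20 stress, Nootripathu control and Nootripathu stress. The labels call the replicates biological and give no further detail, such as whether plants were pooled. Groups were compared with limma 3.58.1 in R 4.3.3: 1 mean per group, 4 residual degrees of freedom, and a moderated test with prior degrees of freedom of 3.88 and a prior standard deviation of 0.129. The comparisons were stress minus control in each cultivar, the difference of those effects (Nootripathu minus IR20), and Nootripathu minus IR20 in control and in stressed roots. P values were adjusted by Benjamini and Hochberg over the 57258 probe sets of a comparison, and a probe set passed at an adjusted p under 0.05. An exact two-sided permutation test of 2 against 2 arrays cannot give a p under 0.333, so no such test was made. The overlap of the drought responses was set against the product of the shares in each cultivar.

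Of the probe sets, 22436 belonged to exactly 1 gene in the annotation, covering 17905 genes, of which 2455 carried a name beyond a locus number. Genes were identified by symbol and locus; the probe set with the highest mean signal stood for its gene. Chromosome positions were not used here. Lists of 34 gene groups and cell type markers and 30 single genes were fixed before the data were examined. The lists had been written for gene descriptions, so they were rewritten as lists of symbols once the annotation was seen and before any comparison was computed, when a list of SnRK2 kinases was also added; they therefore hold only named members. Some members go beyond the descriptions fixed at first, such as CDKB2-1 among the markers of dividing cells and PETC among those of photosynthetic tissue. By symbol, 18 of the 30 single genes were found. The 33 lists with at least 5 genes were tested with camera at a correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated and with fry. Root hair markers had 0 measured genes and the class III peroxidase list 4, so neither was tested; the peroxidase list holds R1C-PRX by its symbol, although that gene encodes a peroxiredoxin. With an estimated correlation 0 lists passed in any comparison.

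Genes to be named were chosen by a rule also fixed in advance, in which carrying a name took the place of carrying a description: among such genes that passed and whose groups did not overlap, the 10 largest rises and falls per drought comparison (8 for the others), up to 2 per direction in each list, and the single genes. The rule gave 665 results for 306 genes, of which 627 passed; the text names those of the groups it describes. The named genes are a part of the 17905 measured, so larger changes can lie in genes without a name. Array signals ran from minima of 2.53 to 2.64 to maxima of 14.9 to 15.3, and changes that end near either limit are bounds.

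Alternatives fixed in advance were the replicate number as a block, a fit of only the arrays compared, leaving out the 40% of probe sets with the lowest signal, median-centring, renewed quantile normalisation, a trended and a trended robust prior, array weights, leaving out probe sets that may match several transcripts, a 2-fold minimum, and leaving out each array in turn. Scaling each array to the 12 probe sets for the 3′ ends of the poly-A spike-in transcripts was added after the control probe sets had been seen. In that fit the differences between replicates in spike-in signal are shared by all probe sets while the test treats them as independent, so its values serve mainly as values. Stressed IR20 replicate 2 was left out as one of the fixed alternatives, and its counts are given in the text because of its spike-in signal.

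The fit was tested on simulated data with the 8 arrays' design and 57258 probe sets. Of changes of 0.5 on the log2 scale it recovered 4.55%, of changes of 1, 52.2%, and of changes of 2, 91%. It made 103 calls, 4 of them false. Only 66 or 67 probe sets were changed at each size, far fewer than passed in the real comparisons. The adjusted threshold depends on the share changed, so these percentages do not give the power of the real fit. In simulated lists over 17905 genes, shifting 1 list by −0.5 gave 1 list past the threshold, the shifted one. The simulated noise was independent between genes, so the list check does not test the assumed correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.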

Results

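Transcript levels were measured in roots of 2 indica rice cultivars, IR20 and Nootripathu, with an Affymetrix rice genome array. The labels describe IR20 as a shallow-rooted, drought-susceptible, semi-dwarf cultivar and Nootripathu as a deep-rooted landrace. Plants grew singly in pipes 1 m long in a greenhouse, and water was withheld from 40 days after sowing in the stressed plants. The 4 groups (each cultivar, control and stressed) held 2 biological replicates each, 1 array per replicate, so 8 arrays in all. Control roots were rinsed in de-ionised water and stressed roots were only tapped free of soil, so that handling and drought changed together in every comparison of stressed with control roots. Differences are given on the log2 scale with their standard error (SE), with n = 2 arrays per group, and the number of arrays limits their precision. The SE of a probe set rests on 1 spread estimated over all 4 groups. It therefore does not show the spread within the groups compared. Adjusted p values come from limma. Each of the genes named for the largest differences within a cultivar or between the cultivars had both arrays of 1 group above both arrays of the other. Rankings cover only the 2455 of 17905 genes with a name, and larger differences can lie in genes without one. Some named genes rest on probe sets that may match several transcripts, so their values may include related transcripts. Examples are NRT2.3, NRT2.2, TIP2-1, TIP3-1, HSP18.6, LSI6, ABA8OX2, EXPB4, LEA3 and MCM9. Of the 665 named results, 584 remained when such probe sets were left out.

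The first comparison asked what drought changed in IR20 roots. RAB25 (LOC4326935), placed here among the late embryogenesis abundant (LEA) proteins and dehydrins, rose by 5.96 ± 0.14, and the small heat shock protein genes HSP16.9A (LOC4325697), HSP18.6 (LOC4330933) and HSP18.0 (LOC4325342) rose by 5.29 ± 0.14, 4.44 ± 0.12 and 4.19 ± 0.15. Among the largest measured falls were those of a peroxidase gene (LOC4339222), at −8.21 ± 0.16, and of TIP2-1 (LOC4330207), which encodes a water channel of the vacuolar membrane, at −8.12 ± 0.24. Falls of 4 transporter genes were also among the 10 largest measured in named genes. The silicon transporter LSI2 (LOC4331328) was at −6.998 ± 0.18, the ammonium transporter AMT1-2 (LOC4330008) at −6.95 ± 0.09, the manganese transporter NRAMP5 (LOC4342859) at −6.49 ± 0.16 and the nitrate transporter NRT2.3 (LOC4324249) at −6.38 ± 0.15.

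Other genes with the largest rises were the chitinase gene CHT1 (4.92 ± 0.13), the 1-Cys peroxiredoxin gene R1C-PRX (4.78 ± 0.10), the vacuolar water channel gene TIP3-1 (4.78 ± 0.11), ELA3 (4.76 ± 0.14), the protein phosphatase gene PP2C59 (4.60 ± 0.11) and the sugar transporter gene SWEET1B (4.39 ± 0.20). Among the falls were also CASPL1U3, of the family of Casparian strip membrane proteins (−6.69 ± 0.30), ILL3 (−6.08 ± 0.20), NAAT1, which acts in phytosiderophore synthesis (−5.98 ± 0.11), and ALN, which encodes allantoinase (−5.94 ± 0.12). Adjusted p of these 20 genes lay between 8.59e-08 and 1.33e-06. The mean stressed signals of the peroxidase gene (2.91), NAAT1 (3.51), AMT1-2 (3.52) and CASPL1U3 (3.64) were near the lowest on the arrays (2.53 to 2.64). Their falls, and the order of the falls, are therefore measured values that background limits.

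**Figure D1:**
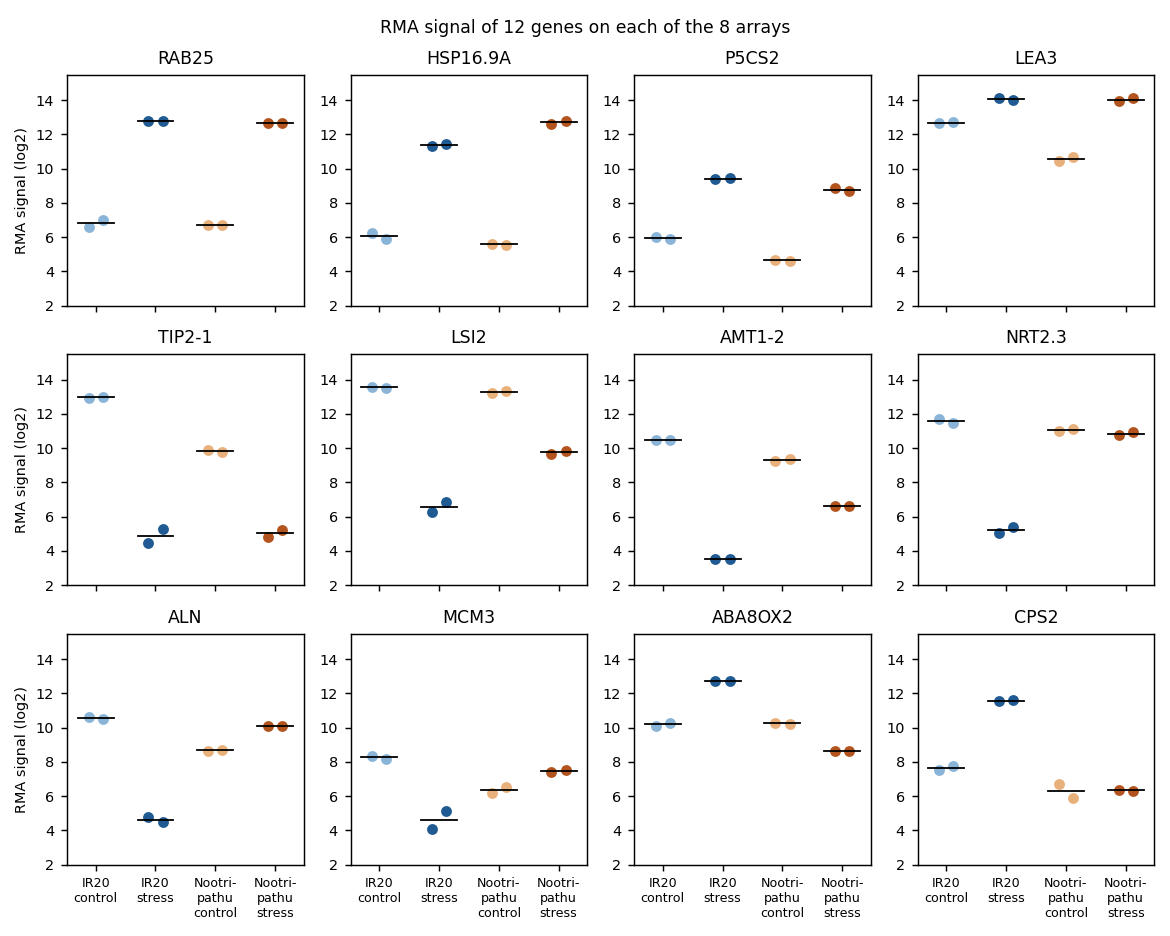
RMA signal (log2, vertical axis) of 12 genes in the 4 groups (horizontal axis); each point is 1 array and each line the mean of the 2 arrays of a group. RAB25 and HSP16.9A were high in both stressed groups, whereas ALN and NRT2.3 were low only on the 2 arrays of stressed IR20 roots.

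Of the 57258 probe sets tested, 21807 passed in IR20, 12000 higher and 9807 lower under drought, and 8713 of them differed at least 2-fold. Among these 8713 the balance was the other way, with 3700 higher and 5013 lower. Genes of the LEA and dehydrin list rose together: 7 of 8 rose and 0 fell, with a median of 1.94 and EMP1 at 3.81 ± 0.22 (camera adjusted p = 0.00119, adjusted p = 0.26 with an estimated correlation). Among the heat shock proteins 14 of 25 genes rose and 7 fell, HSP18.8 by −3.40 ± 0.16, and the median was 1.04 (adjusted p = 0.0231, adjusted p = 0.398 with an estimated correlation). Of the heat stress factors, the regulators of those genes, 12 of 20 rose and 1 fell (median 1.08, adjusted p = 0.00177, adjusted p = 0.382 with an estimated correlation); HSFA6B rose by 3.56 ± 0.10 and HSFC1A fell by 1.14 ± 0.23. With the arrays scaled to spike-in transcripts added to the RNA, the heat shock proteins rose in 9 cases and fell in 7 (median 0.43), and the heat stress factors rose in 6 and fell in 4 (median 0.47). Adjusted over the list alone, 7 genes of the first list rose, 14 of the second rose and 7 fell, and 12 of the third rose and 1 fell.

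Water channels, wall-loosening proteins and genes of nitrate and ammonium uptake and assimilation went down in IR20. Of the aquaporins 20 of 25 fell and 2 rose, with a median of −1.14 (adjusted p = 0.00158, adjusted p = 0.407 with an estimated correlation). LSI6 fell by 5.26 ± 0.17 and TIP3-2 rose by 1.24 ± 0.16, and adjusted over the list alone 20 fell and 3 rose. Expansins and xyloglucan endotransglucosylases, which loosen cell walls, fell in 18 of 30 genes and rose in 1, with a median of −0.91 (adjusted p = 0.000427, adjusted p = 0.26 with an estimated correlation). EXPB3 stood at −5.92 ± 0.16, and adjusted over the list alone 20 fell and 2 rose. Nitrate and ammonium uptake and assimilation genes fell in 13 of 18 cases and rose in 3, with a median of −1.81 (adjusted p = 0.00177, adjusted p = 0.26 with an estimated correlation). The glutamine synthetase gene GLN1-3 was among the rises, at 3.62 ± 0.14, and adjusted over the list alone 13 fell and 3 rose.

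Genes of wall synthesis, cell division and jasmonate synthesis fell as well. Of the cellulose synthases and their relatives 19 of 29 fell and 2 rose, with a median of −1.08 (adjusted p = 0.000427, adjusted p = 0.382 with an estimated correlation). CSLA1 fell by 5.68 ± 0.20 and CSLA5 rose by 1.54 ± 0.12, and adjusted over the list alone 21 fell and 2 rose. Lignin synthesis genes fell in 17 of 30 cases and rose in 4, with a median of −0.56 (adjusted p = 0.0231, adjusted p = 0.563 with an estimated correlation). The cinnamyl alcohol dehydrogenase gene CAD8A stood at −5.89 ± 0.26, and adjusted over the list alone 17 fell and 5 rose. In the list for jasmonate synthesis and TIFY proteins 23 of 35 genes fell and 4 rose, with a median of −0.82 (adjusted p = 0.000672, adjusted p = 0.407 with an estimated correlation). AOS4 fell by 5.45 ± 0.11 and OPR5 by 5.33 ± 0.24, and adjusted over the list alone 24 fell and 4 rose. Markers of dividing cells (cyclins, replication helicase subunits, histones) fell in 17 of 21 cases and rose in 1, with a median of −2.24 (adjusted p = 0.000138, adjusted p = 0.407 with an estimated correlation). CYCB2 (LOC4342121) fell by 5.30 ± 0.25 and CDKB2-1 by 4.09 ± 0.13, and adjusted over the list alone 17 fell and 1 rose. Ribosomal protein genes fell in 12 of 25 cases and rose in 0, with a median of −0.24 (adjusted p = 0.0157, adjusted p = 0.427 with an estimated correlation; adjusted over the list alone, 12 fell).

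Of the genes fixed one by one in advance, HSP101 (2.13 ± 0.13), DREB2A (2.81 ± 0.13), LEA3 (1.37 ± 0.11), RAB16A (1.37 ± 0.11), P5CS1 (1.18 ± 0.09), HsfA2a (1.10 ± 0.14), SalT (0.84 ± 0.10), ABA8ox1 (0.74 ± 0.11) and PP2C30 (0.51 ± 0.09) rose in IR20. With the arrays scaled to the spike-in transcripts RAB16A (0.77), LEA3 (0.76), P5CS1 (0.57), HsfA2a (0.49), SalT (0.23), ABA8ox1 (0.14) and PP2C30 (−0.10) did not pass. NAS1 (−5.56 ± 0.25) and IRT1 (−3.38 ± 0.13), of iron acquisition, fell, as did NAC5 (−1.20 ± 0.35, or −0.55 without stressed IR20 replicate 2), PDC1 (−1.11 ± 0.13) and DREB1A (−1.03 ± 0.10). The values of bZIP23 (0.15 ± 0.09), NAC6 (0.16 ± 0.09), SD1 (0.19 ± 0.13) and LIP9 (−0.15 ± 0.10) did not pass. The proline synthesis gene P5CS2 rose by 3.47 ± 0.10. RAB16A reached 15.3 under stress, the highest signal on the arrays (15.3), so its rise is a lower bound.

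The array of stressed IR20 replicate 2 stood apart: the 3′ signal of the added poly-A spike-in transcripts exceeded the 5′ signal by 5.44, against 2.31 to 2.67 on the other 7 arrays. For transcripts of the root itself the excess was 6.14 for actin, against 3.55 to 4.56, and 6.47 for GAPDH, against 2.92 to 3.79. Without that array 21609 probe sets passed in IR20, 18740 of them shared with the full fit, and the same 11 lists passed. Without the other stressed IR20 array, 10 of the 11 passed, and the rising lists went from 3 to 2. Under spike-in scaling the ribosomal protein list did not pass (adjusted p = 0.497).

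The same question in Nootripathu roots gave a partly shared picture. HSP16.9A rose by 7.12 ± 0.14, HSP16.9B (LOC4325698) by 6.06 ± 0.17 and HSP18.0 by 4.76 ± 0.15. RAB25, EMP1 (LOC4338499) and RAB16C (LOC4350452), of the LEA and dehydrin list, rose by 5.95 ± 0.14, 5.52 ± 0.22 and 5.05 ± 0.12. Among the largest measured falls were those of CASPL1C1 (LOC4327789), at −5.38 ± 0.25, CASPL1U3, at −5.35 ± 0.30, and the germin-like genes GER1 (LOC4344840) and GLP2 (LOC4344846), at −5.17 ± 0.17 and −4.88 ± 0.19.

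R1C-PRX (5.84 ± 0.10), the lipid transfer protein gene LTP-2 (5.34 ± 0.12), SWEET12 (4.96 ± 0.19) and ELA3 (4.79 ± 0.14) completed the 10 largest rises of named genes. TIP2-1 (−4.79 ± 0.24), CAD8A (−4.66 ± 0.26), the nicotianamine synthase gene NAS1 (−4.52 ± 0.25), OPR5 (−4.44 ± 0.24), EXPA8 (−4.42 ± 0.24) and AOS4 (−4.33 ± 0.11) completed the 10 largest measured falls of named genes. Adjusted p of the 20 genes lay between 4.68e-08 and 5.94e-06. In all, 18267 probe sets passed, 10001 higher and 8266 lower, and 7199 of them differed at least 2-fold, 3570 higher and 3629 lower.

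LEA and dehydrin genes rose in 7 of 8 cases and fell in 1 (LIP9, −0.34 ± 0.10), with a median of 3.97 (adjusted p = 0.000666, adjusted p = 0.298 with an estimated correlation). Glutathione S-transferases, enzymes of detoxification, rose in 5 of 6 cases and fell in 0; GST-I rose by 2.78 ± 0.14 and the median was 1.18, or 0.29 under spike-in scaling (adjusted p = 0.0138, adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone, 7 rose and 1 fell in the first list and 5 rose in the second. Heat shock proteins rose in 15 of 25 cases and fell in 5, but the list did not pass (adjusted p = 0.0708), and its median of 0.80 was −0.10 under spike-in scaling.

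Aquaporins fell in 14 of 25 cases and rose in 3, with a median of −0.55 (adjusted p = 0.00477, adjusted p = 0.46 with an estimated correlation). PIP2-2, a channel of the plasma membrane, stood at −3.24 ± 0.13, and adjusted over the list alone 14 fell and 3 rose. In the expansin list 15 of 30 genes fell and 2 rose, with a median of −0.52 (adjusted p = 0.00175, adjusted p = 0.298 with an estimated correlation). EXPA5 stood at −3.15 ± 0.10, and adjusted over the list alone 17 fell and 4 rose. Lignin synthesis genes fell in 18 of 30 cases and rose in 2, with a median of −0.95 (adjusted p = 0.000666, adjusted p = 0.46 with an estimated correlation). The laccase gene LAC10 rose by 4.03 ± 0.12, LAC15 fell by 2.74 ± 0.19, and adjusted over the list alone 18 fell and 4 rose. Nitrate and ammonium genes fell in 10 of 18 cases and rose in 4, with a median of −0.56 (adjusted p = 0.0233, adjusted p = 0.345 with an estimated correlation). AMT1-2 fell by 2.71 ± 0.09, while NAR2.2, a partner protein of nitrate transporters, rose by 3.86 ± 0.18, and adjusted over the list alone 10 fell and 4 rose.

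Iron and nicotianamine genes fell in 9 of 26 cases and rose in 2, with a median of −0.20 (adjusted p = 0.013, adjusted p = 0.46 with an estimated correlation). NAS2 fell by 4.21 ± 0.20, and adjusted over the list alone 12 fell and 2 rose. NAC transcription factors fell in 5 of 8 cases and rose in 0, with a median of −0.83 (adjusted p = 0.0138, adjusted p = 0.345 with an estimated correlation). NAC068 stood at −2.14 ± 0.10, and adjusted over the list alone 7 fell. Jasmonate and TIFY genes fell in 20 of 35 cases and rose in 2, with a median of −0.52 (adjusted p = 0.000336, adjusted p = 0.46 with an estimated correlation; adjusted over the list alone, 22 fell and 3 rose). Markers of dividing cells rose in 6 of 21 cases and fell in 6, with a median of −0.02, and did not pass as a list (adjusted p = 0.727). Under spike-in scaling 0 rose and 14 fell, with a median of −0.915.

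Among the genes fixed in advance, LEA3 (3.48 ± 0.11), RAB16A (3.23 ± 0.11), HSP101 (2.03 ± 0.13), PDC1 (1.99 ± 0.13), DREB2A (1.68 ± 0.13), ABA8ox1 (1.40 ± 0.11) and SalT (1.17 ± 0.10) rose in Nootripathu. P5CS1 (0.75 ± 0.09) and HsfA2a (0.49 ± 0.14) rose too. Under spike-in scaling ABA8ox1 (0.50), SalT (0.27), P5CS1 (−0.15) and HsfA2a (−0.40) did not pass, whereas NAC6 (−1.14), DREB1A (−1.08) and bZIP23 (−0.97) passed as falls. The scaling lowers every difference in Nootripathu by the same 0.89, so most of these 3 falls is that shift. IRT1 (−1.48 ± 0.13), NAC5 (−1.33 ± 0.35), SD1, the gibberellin oxidase gene of semi-dwarf rice (−1.07 ± 0.13), and PP2C30 (−0.36 ± 0.09) fell. DREB1A (−0.19 ± 0.10), NAC6 (−0.25 ± 0.09) and bZIP23 (−0.07 ± 0.09) did not pass. The stressed signal of RAB16A was again at the top of the arrays (15.3), so its rise is a lower bound here too.

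**Figure D2:**
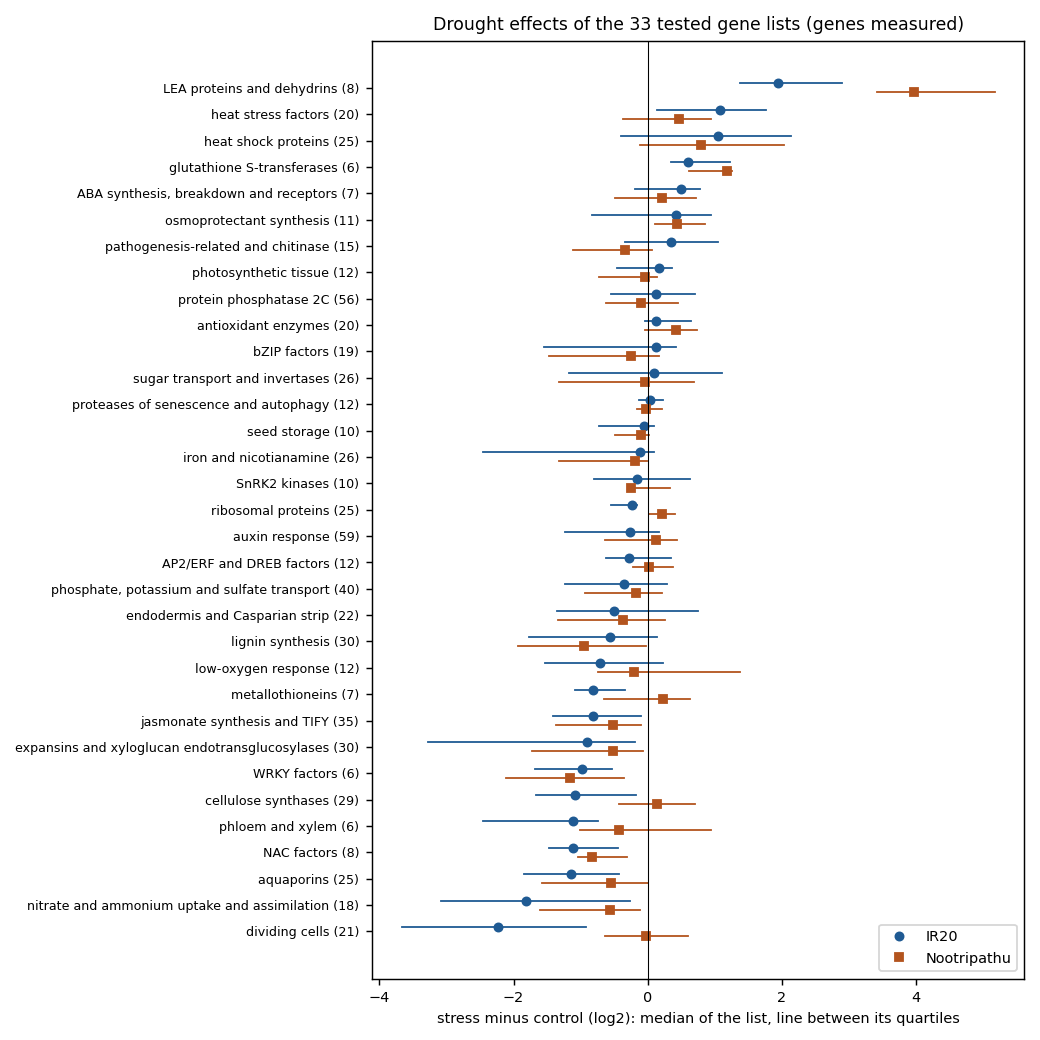
Median difference between stressed and control roots (log2, horizontal axis) of each of the 33 tested gene lists in IR20 (circles) and Nootripathu (squares); lines join the quartiles of a list and the number of genes stands in parentheses. Markers of dividing cells had a median of −2.24 in IR20 and −0.02 in Nootripathu, and the LEA and dehydrin list 1.94 and 3.97. Under spike-in scaling these medians were −2.85, −0.915, 1.33 and 3.08.

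The 3′ ends of the poly-A spike-in transcripts, added to the RNA as controls, gave more signal on the stressed arrays, by 0.61 in IR20 and 0.89 in Nootripathu. Their 5′ ends differed by −0.70 in IR20 and 0.98 in Nootripathu. The 3′ signal of stressed IR20 was 11.09 on replicate 1 and 10.51 on replicate 2, so the IR20 value depends on the array. With the arrays scaled to the 3′ signals the median of all probe sets was −0.51 in IR20 and −0.90 in Nootripathu, against 0.10 and −0.000915 as deposited. Under this scaling 16771 probe sets passed in IR20, 12.2% of them higher, and 43988 in Nootripathu, 3.35% of them higher. The nitrate and NAC lists then did not pass in Nootripathu (adjusted p = 0.303 and 0.0739).

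The responses of the cultivars overlapped. Of all probe sets, 6185 were higher under drought in both, where 2096 would be by chance, and 5294 were lower in both, where 1416 would be by chance. A further 1217 passed in both in opposite directions, for which no chance value was computed. The chance values ignore that both comparisons use the same estimate of the spread, so that probe sets with a small spread tend to pass in both. Under spike-in scaling 892 were higher in both (52.7 by chance) and 12603 lower in both (10930 by chance). Pearson's r of the 2 effects was 0.689 across probe sets, which are not independent replicates. Of the named genes, RAB25, HSP16.9A, HSP18.0, R1C-PRX and ELA3 were among the 10 largest rises in each cultivar. TIP2-1 and CASPL1U3 were among the 10 largest falls in each. The shared rises included P5CS2 (4.13 ± 0.10 in Nootripathu) and PP2C59 (4.41 ± 0.11 in Nootripathu).

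The next comparison asked where the cultivars responded differently: the drought effect in Nootripathu minus that in IR20, tested as an interaction. Allantoinase (ALN) had the largest difference of the named genes, at 7.36 ± 0.17. Its mean signal went from 10.6 in control to 4.63 in stressed IR20 roots, and from 8.68 to 10.1 in Nootripathu. NRT2.3 followed at 6.15 ± 0.21, then ILL3 at 4.99 ± 0.28, the replication protein gene RPA32 at 4.90 ± 0.18, the replication helicase genes MCM3 and MCM4 at 4.80 ± 0.41 and 4.66 ± 0.38, BC1 (LOC4333114) of secondary wall formation at 4.72 ± 0.13 and the peroxidase gene LOC4339222 at 4.56 ± 0.23. In the other direction stood ABA8OX2, which encodes an enzyme that breaks down abscisic acid, at −4.16 ± 0.15; it rose by 2.54 ± 0.11 in IR20 and fell by 1.62 ± 0.11 in Nootripathu. CPS2, of diterpenoid phytoalexin synthesis, was at −3.90 ± 0.33, the transporter gene ABCG32 at −3.82 ± 0.15, PP2C61 at −3.50 ± 0.15, CHT1 at −3.49 ± 0.19, IRL2 at −3.47 ± 0.15, PSK4 at −3.23 ± 0.26 and GER1 at −3.10 ± 0.24. Adjusted p of these 16 genes lay between 3.67e-06 and 0.000194. For 2 of them the difference mirrors the control level, since the stressed signals lay close together. ILL3 went from 10.2 to 4.13 in IR20 and from 5.31 to 4.22 in Nootripathu, and the peroxidase gene from 11.1 to 2.91 and from 6.84 to 3.19, near the lowest signals on the arrays. For IRL2, PP2C61, BC1 and, by little, RPA32 the cultivars also differed more in control than under stress. Their stressed signals differed too, in the opposite direction.

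In this test 11204 probe sets passed, 6059 positive and 5145 negative. The effect was larger in size in IR20 for 6867 and in Nootripathu for 4337. Of the 11204, 4024 passed for drought in IR20 and not in Nootripathu, 2434 in Nootripathu and not in IR20, and 3295 in both in the same direction.

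Markers of dividing cells had a positive difference in 15 of 21 cases and a negative one in 0, with a median of 1.87 (adjusted p = 6.27e-05, adjusted p = 0.59 with an estimated correlation; adjusted over the list alone, 16 positive). Between the cultivars their median was −1.19 in control and 0.45 in stressed roots, so that much of this difference lay in the control level. Cellulose synthases were positive in 20 of 29 cases and negative in 0, with a median of 1.35 (adjusted p = 7.79e-05, adjusted p = 0.38 with an estimated correlation). CSLC3 stood at 3.16 ± 0.18 and CSLA1 at 3.03 ± 0.28, and adjusted over the list alone 20 were positive and 2 negative. Between the cultivars the cellulose synthase median was −0.77 in control and 0.41 in stressed roots. Nitrate and ammonium genes were positive in 11 of 18 cases and negative in 1, with a median of 1.18 (adjusted p = 0.000386, adjusted p = 0.38 with an estimated correlation). AMT1-2 stood at 4.24 ± 0.13 and AMT2-3 at −2.46 ± 0.21, and adjusted over the list alone 13 were positive and 1 negative. Ribosomal proteins were positive in 15 of 25 cases and negative in 0, with a median of 0.56 (adjusted p = 0.000386, adjusted p = 0.38 with an estimated correlation). Between the cultivars their median was −0.45 in control, with 15 lower in Nootripathu, and 0.16 in stressed roots, with 2 higher. Most of this difference therefore lay in the control level. RPL3 stood at 1.18 ± 0.32 (0.77 without stressed IR20 replicate 2) and RPS26 at 1.06 ± 0.14, and adjusted over the list alone 19 were positive; under spike-in scaling the list did not pass (adjusted p = 0.133). LEA and dehydrin genes were positive in 6 of 8 cases and negative in 0, with a median of 1.91 (adjusted p = 0.00534, adjusted p = 0.38 with an estimated correlation). RAB16C stood at 2.46 ± 0.17 and LEA3 at 2.11 ± 0.16, and adjusted over the list alone 6 were positive. These 2 genes ended at close signals under stress (14.5 and 14.3, 14.1 and 14.0) from a lower control level in Nootripathu. RAB16A, at 1.86 ± 0.15, was at the top of the arrays in both stressed groups, so its value gives the control difference and not how the responses differ.

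Auxin response genes were positive in 21 of 59 cases and negative in 2, with a median of 0.47 (adjusted p = 0.00534, adjusted p = 0.857 with an estimated correlation). IAA12 stood at 3.50 ± 0.25, IAA31 at 2.71 ± 0.16, SAUR39 at −1.94 ± 0.17 and GH3-8 at −0.60 ± 0.16, and adjusted over the list alone 30 were positive and 4 negative. Expansins and their relatives were positive in 13 of 30 cases and negative in 2, with a median of 0.30 (0.01 under spike-in scaling; adjusted p = 0.04, adjusted p = 0.38 with an estimated correlation). EXPB3 stood at 4.55 ± 0.22 and EXPB4 at 3.63 ± 0.23, and adjusted over the list alone 13 were positive and 2 negative. Between the cultivars the expansin median was −0.32 in control and 0.02 in stressed roots, so most of this difference lay in the control level. Without stressed IR20 replicate 2 this list did not pass (adjusted p = 0.193). Negative lists were the heat stress factors, negative in 7 of 20 cases and positive in 1, with a median of −0.38 (adjusted p = 0.00301, adjusted p = 0.38 with an estimated correlation). HSFB2A stood at −2.36 ± 0.15, HSFB2B at −2.24 ± 0.35 and HSFC1A at 2.38 ± 0.33, and adjusted over the list alone 10 were negative and 1 positive. Pathogenesis-related proteins and chitinases were negative in 8 of 15 cases and positive in 1, with a median of −0.86 (adjusted p = 0.00254, adjusted p = 0.38 with an estimated correlation). PBZ1 stood at −2.40 ± 0.19, and adjusted over the list alone 9 were negative and 1 positive. Protein phosphatases 2C were negative in 15 of 56 cases and positive in 1 (PP2C28, 0.84 ± 0.15), with a median of −0.12 (adjusted p = 0.0188, adjusted p = 0.857 with an estimated correlation). PP2C69 stood at −2.04 ± 0.20, and adjusted over the list alone 16 were negative and 2 positive. Without stressed IR20 replicate 2, 13 phosphatase genes were negative and 9 positive.

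Without stressed IR20 replicate 2, the array with the high 3′ to 5′ ratio, the median of the dividing cell markers in this comparison was 2.16. Without stressed IR20 replicate 1 it was 1.74. More probe sets passed when either stressed IR20 array was left out, so the gain is not particular to the array with the high ratio. Fewer probe sets passed when any other array was left out. Under spike-in scaling 3228 probe sets passed.

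The cultivars were also compared without drought, as Nootripathu minus IR20 in control roots. EIL1 (LOC4332697) was higher in Nootripathu by 6.70 ± 0.27 and the calcium-dependent kinase gene CPK21 (LOC4346187) by 4.77 ± 0.13. BURP2 (LOC4338119) and ILL3 were lower, at −4.95 ± 0.15 and −4.90 ± 0.20. LEA and dehydrin genes were lower in Nootripathu in 6 of 8 cases and higher in 1, with a median of −2.01 (adjusted p = 0.0105, adjusted p = 0.454 with an estimated correlation). RAB16C stood at −2.61 ± 0.12, LEA3 at −2.13 ± 0.11 and RAB16A at −1.86 ± 0.11, and adjusted over the list alone 6 were lower and 1 higher. Markers of dividing cells were lower in 16 of 21 cases and higher in 0, with a median of −1.19 (adjusted p = 5.56e-05, adjusted p = 0.505 with an estimated correlation). CYCB2 (LOC4342121) stood at −3.16 ± 0.25, and adjusted over the list alone 17 were lower.

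Further genes higher in Nootripathu were CCS1 (3.51 ± 0.21), MCM9 (3.51 ± 0.15), AGGLUTININ (3.07 ± 0.12), the cystatin gene OC-IV (2.77 ± 0.13), IRL2 (2.69 ± 0.11) and CYP714C2 (2.47 ± 0.25). Lower ones were CHARK (−4.41 ± 0.26), FIL2 (−4.35 ± 0.25), the peroxidase gene LOC4339222 (−4.28 ± 0.16), LTP110-A (−4.13 ± 0.13), EXPB3 (−4.10 ± 0.16) and LSI6 (−3.94 ± 0.17). Adjusted p of these 16 genes lay between 4.09e-07 and 0.000287. Of all probe sets 11048 passed, 4792 higher and 6256 lower, and 3763 differed at least 2-fold. Under spike-in scaling the balance turned, with 2651 higher and 2059 lower. Of the genes fixed in advance SD1 was higher by 1.13 ± 0.13 and DREB2A by 0.71 ± 0.13, and SalT (−2.23 ± 0.10), IRT1 (−1.60 ± 0.13) and NAS1 (−1.45 ± 0.25) were lower.

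Cellulose synthases were lower in 17 of 29 cases and higher in 4, with a median of −0.77 (adjusted p = 0.0201, adjusted p = 0.505 with an estimated correlation). CSLC3 stood at −2.73 ± 0.13, and adjusted over the list alone 18 were lower and 5 higher. Ribosomal proteins were lower in 15 of 25 cases and higher in 0, with a median of −0.45 (adjusted p = 0.00704, adjusted p = 0.505 with an estimated correlation). RPS4 stood at −0.83 ± 0.10, and adjusted over the list alone 17 were lower. WRKY factors were higher in 4 of 6 cases and lower in 0, with a median of 0.64 (adjusted p = 0.0201, adjusted p = 0.454 with an estimated correlation). WRKY76 stood at 0.99 ± 0.10, and adjusted over the list alone 4 were higher. NAC factors were higher in 5 of 8 cases and lower in 0, with a median of 0.54 (adjusted p = 0.0201, adjusted p = 0.454 with an estimated correlation). NAC010 stood at 1.27 ± 0.21, and adjusted over the list alone 6 were higher and 1 lower. Heat stress factors were higher in 8 of 20 cases and lower in 2, with a median of 0.29 (adjusted p = 0.0199, adjusted p = 0.505 with an estimated correlation). HSFA9 stood at 1.30 ± 0.10, and adjusted over the list alone 11 were higher and 2 lower. Protein phosphatases 2C were higher in 15 of 56 cases and lower in 7, with a median of 0.11 (adjusted p = 0.0338, adjusted p = 0.747 with an estimated correlation). PP2C61 stood at 2.36 ± 0.10, and adjusted over the list alone 17 were higher and 8 lower. Under spike-in scaling 3 of these 8 lists passed (LEA and dehydrins, cellulose synthases, dividing cells), and 4710 probe sets did. Without stressed IR20 replicate 2, which enters through the shared estimate of the spread, the cellulose synthase list did not pass (adjusted p = 0.0572).

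The last comparison was Nootripathu minus IR20 in stressed roots. EIL1 (5.93 ± 0.27) and CPK21 (5.46 ± 0.13) were again higher in Nootripathu, followed by NRT2.3 (5.64 ± 0.15), ALN (5.47 ± 0.12), SWEET12 (4.17 ± 0.19), NAR2.2 (4.11 ± 0.18), AGGLUTININ (3.94 ± 0.12) and the nitrate transporter gene NRT2.2 (3.72 ± 0.13). Lower in Nootripathu were CPS2 (−5.24 ± 0.23), ABCG32 (−4.46 ± 0.10), ABA8OX2 (−4.11 ± 0.11), PBZ1 (−3.73 ± 0.13), the diterpene synthase gene KS10 (−3.63 ± 0.15), BURP2 (−3.48 ± 0.15), DRB3 (−3.46 ± 0.15) and LAC19 (−3.44 ± 0.14). Adjusted p of these 16 genes lay between 1.4e-07 and 3.89e-06. Of the LEA and dehydrin genes 0 of 8 passed in either direction, with a median of −0.06. Of all probe sets 12601 passed, 6105 higher and 6496 lower, and 3587 differed at least 2-fold, 2295 higher and 1292 lower. Under spike-in scaling 2547 were higher and 1839 lower.

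Nitrate and ammonium genes were higher in Nootripathu in 8 of 18 cases and lower in 2, with a median of 0.53 (adjusted p = 0.0103, adjusted p = 0.757 with an estimated correlation; adjusted over the list alone, 9 higher and 2 lower). Genes of the phloem and xylem list were higher in 5 of 6 cases and lower in 0, with a median of 1.27 (adjusted p = 0.00664, adjusted p = 0.757 with an estimated correlation). Most members are BC1 and BC1-like (BC1L) genes, so the list does not measure those tissues as such. RPP16 stood at 1.73 ± 0.11 and BC1 at 1.71 ± 0.09, and adjusted over the list alone 5 were higher. Markers of dividing cells were higher in 9 of 21 cases and lower in 1, with a median of 0.45 (adjusted p = 0.0283, adjusted p = 0.787 with an estimated correlation). MCM4 stood at 3.10 ± 0.27 and H2B.10 at −1.94 ± 0.13, and adjusted over the list alone 9 were higher and 1 lower. Cellulose synthases were higher in 15 of 29 cases and lower in 2, with a median of 0.41 (adjusted p = 0.0283, adjusted p = 0.757 with an estimated correlation). CSLC9 stood at 1.96 ± 0.13, and adjusted over the list alone 16 were higher and 3 lower. Auxin response genes were higher in 19 of 59 cases and lower in 4, with a median of 0.27 (adjusted p = 0.00664, adjusted p = 0.787 with an estimated correlation). IAA6 stood at 1.70 ± 0.20, and adjusted over the list alone 25 were higher and 5 lower. Jasmonate and TIFY genes were higher in 17 of 35 cases and lower in 4, with a median of 0.48 (adjusted p = 0.00664, adjusted p = 0.757 with an estimated correlation). JAZ13 stood at 1.19 ± 0.15, and adjusted over the list alone 19 were higher and 4 lower.

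Pathogenesis-related proteins and chitinases were lower in Nootripathu in 9 of 15 cases and higher in 1, with a median of −0.52 (adjusted p = 0.0283, adjusted p = 0.757 with an estimated correlation). CHT1 stood at −1.89 ± 0.13, and adjusted over the list alone 9 were lower and 2 higher. Photosynthetic tissue markers were lower in 4 of 12 cases and higher in 0, with a median of −0.43 (adjusted p = 0.0255, adjusted p = 0.757 with an estimated correlation). PETC stood at −2.13 ± 0.15, and adjusted over the list alone 6 were lower. Without stressed IR20 replicate 2 the cellulose synthase and photosynthetic lists did not pass (adjusted p = 0.0741 and 0.0952). Under spike-in scaling these 2 and the auxin and jasmonate lists did not pass (adjusted p = 0.0944, 0.0628, 0.141 and 0.251). Without that replicate the count of probe sets was 12572, of which 9873 were shared. Across both conditions 1887 probe sets were higher and 1479 lower in Nootripathu with and without drought, where 511 and 710 would be by chance. A further 1697 passed in both in opposite directions, for which no chance value was computed. Both comparisons use the same estimate of the spread, so probe sets with a small spread tend to pass in both. The chance values ignore this, and the excess is therefore not a measure of shared cultivar differences alone.

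**Figure D3:**
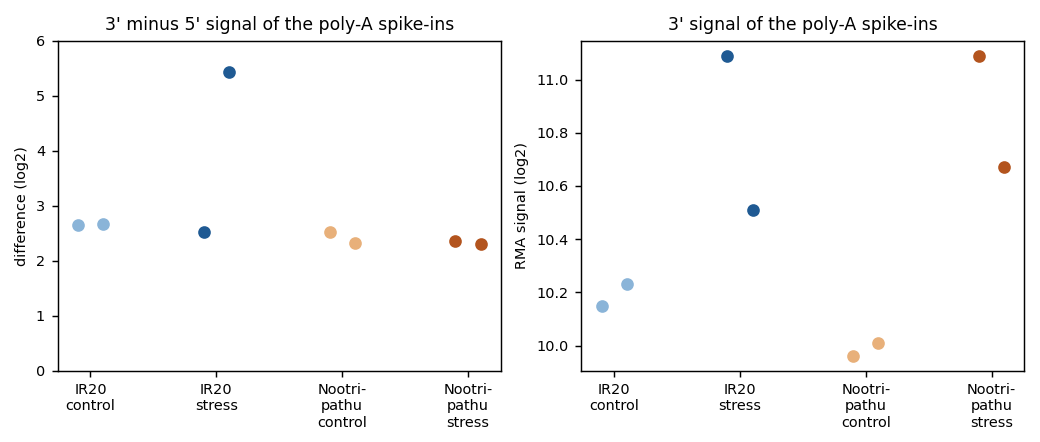
Poly-A spike-in transcripts on each of the 8 arrays (points) in the 4 groups (horizontal axis): 3′ minus 5′ signal (left, log2) and 3′ signal (right, RMA signal, log2). One array of stressed IR20 roots stood at 5.44 on the left, and all stressed arrays lay above all control arrays on the right.

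Several lists did not pass for drought in either cultivar or passed in 1 cultivar alone. In IR20 the protein phosphatases 2C rose in 24 of 56 cases and fell in 15, genes of abscisic acid synthesis, breakdown and receptors rose in 4 of 7 and fell in 1, and osmoprotectant synthesis genes rose in 6 of 11 and fell in 4. Antioxidant enzymes rose in 8 of 20 cases and fell in 0, and glutathione S-transferases rose in 4 of 6 and fell in 0. Iron and nicotianamine genes fell in 12 of 26 cases and rose in 4, and phosphate, potassium and sulfate transporters fell in 22 of 40 and rose in 7. Among regulators, NAC factors fell in 6 of 8 cases, WRKY factors in 5 of 6, AP2/ERF and DREB factors in 4 of 12 with 3 rises, bZIP factors in 8 of 19 with 6 rises and auxin response genes in 26 of 59 with 12 rises. Genes of the Casparian strip list, whose named members were CASP-like (CASPL) genes, fell in 13 of 22 cases and rose in 7. Those of the phloem and xylem list fell in 5 of 6 and rose in 1, and seed storage genes, a check for unrelated tissue, fell in 3 of 10. Photosynthetic tissue markers rose in 2 of 12 cases and fell in 2, and pathogenesis-related genes rose in 7 of 15 and fell in 4. Adjusted over the list alone, the counts differed for protein phosphatases 2C (16 falls), abscisic acid genes (2 falls), glutathione S-transferases (1 fall), phosphate, potassium and sulfate transporters (8 rises and 23 falls), AP2/ERF and DREB factors (6 falls) and auxin response genes (14 rises and 27 falls). The medians of the phosphatase, abscisic acid, osmoprotectant, antioxidant, glutathione S-transferase, bZIP, pathogenesis-related and photosynthetic lists were positive as deposited and negative under spike-in scaling. The means of the bZIP and photosynthetic lists were negative as deposited (−0.60 and −0.09, against medians of 0.12 and 0.16).

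In Nootripathu the protein phosphatases 2C rose in 16 of 56 cases and fell in 22, abscisic acid genes rose in 3 of 7 and fell in 2, osmoprotectant genes rose in 6 of 11 and fell in 1, and antioxidant enzymes rose in 12 of 20 and fell in 1. Cellulose synthases rose in 11 of 29 cases and fell in 9, ribosomal proteins rose in 9 of 25 and fell in 1, and heat stress factors rose in 11 of 20 and fell in 5. Phosphate, potassium and sulfate transporters fell in 15 of 40 cases and rose in 9. AP2/ERF and DREB factors rose in 3 of 12 cases and fell in 2, WRKY factors fell in 4 of 6 and rose in 1, bZIP factors fell in 9 of 19 and rose in 5, and auxin response genes fell in 19 of 59 and rose in 17. Pathogenesis-related genes fell in 6 of 15 cases and rose in 3, and genes of the Casparian strip list fell in 11 of 22 and rose in 5. Those of the phloem and xylem list fell in 3 of 6 and rose in 2, photosynthetic tissue markers fell in 4 of 12 and rose in 1, and seed storage genes fell in 3 of 10. Adjusted over the list alone, the counts differed for protein phosphatases 2C (17 rises and 23 falls), osmoprotectants (7 rises), cellulose synthases (13 rises), phosphate, potassium and sulfate transporters (10 rises and 16 falls), heat stress factors (6 falls), auxin response genes (19 rises), pathogenesis-related genes (7 falls), ribosomal proteins (2 falls), photosynthetic tissue markers (2 rises) and dividing cells (7 rises and 7 falls). The medians of the abscisic acid, osmoprotectant, antioxidant, cellulose synthase, AP2/ERF, heat stress factor, auxin and ribosomal lists were positive as deposited and negative under spike-in scaling. For the auxin list the mean (−0.04) and the test pointed down while the median was 0.12, and for AP2/ERF the test pointed down at a median of 0.02.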

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

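The tests of the 3 patterns weighed below were all chosen only after the results had been seen. The results in the next paragraphs were picked out because the drought effect differed between Nootripathu and IR20 in a test of the difference itself; each value is the effect in Nootripathu minus that in IR20. Those of control probe sets come from data that the comparisons do not use.

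The largest positive differences among these genes were those of ALN (7.36), NRT2.3 (6.15), ILL3 (4.99), RPA32 (4.90), MCM3 (4.80), BC1 (4.72), MCM4 (4.66), the peroxidase gene LOC4339222 (4.56), EXPB3 (4.55), AMT1-2 (4.24), EXPB4 (3.63), IAA12 (3.50), CSLC3 (3.16), CSLA1 (3.03), IAA31 (2.71), AP25 (2.41), HSFC1A (2.38) and IRT1 (1.90). Smaller positive differences were those of RPL3 (1.18), RPS26 (1.06), DREB1A (0.85), PP2C28 (0.84), a chitinase gene (LOC4348631, 0.70) and ABA8ox1 (0.65). RAB16C (2.46) and LEA3 (2.11) belong here too, as does RAB16A (1.86), which was at the highest signal of the arrays in both stressed groups, so that its value shows the control difference alone. PDC1 (3.10) rose in Nootripathu and fell in IR20.

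Negative differences were those of ABA8OX2 (−4.16), CPS2 (−3.90), ABCG32 (−3.82), PP2C61 (−3.50), CHT1 (−3.49), IRL2 (−3.47), PSK4 (−3.23), GER1 (−3.10), AMT2-3 (−2.46), PBZ1 (−2.40), HSFB2A (−2.36), HSFB2B (−2.24), PP2C69 (−2.04), SAUR39 (−1.94), SD1 (−1.26), EXLA1 (−1.26), DREB2A (−1.13), PP2C30 (−0.87), EXPB10 (−0.65), GH3-8 (−0.60) and VPE1 (−0.57). For 15 of the 49 genes in these paragraphs the cultivars differed by under 0.5 under stress and by more in control, so that more of the value lay in the control than in the stressed roots: ILL3, the peroxidase gene, RAB16C, LEA3, RAB16A, PP2C69, EXPB3, CSLC3, DREB2A, GH3-8, RPS26, AP25, VPE1, IRT1 and SD1. The bound of 0.5 leaves out other genes that differed more in control than under stress, such as EXPB4, CSLA1, IAA31, IRL2, PP2C61, BC1 and RPA32. The medians of the lists that differed were 1.91 (LEA and dehydrins), 1.87 (dividing cells), 1.35 (cellulose synthases), 1.18 (nitrate and ammonium), 0.559 (ribosomal proteins), 0.47 (auxin response), 0.296 (expansins), −0.863 (pathogenesis-related proteins), −0.378 (heat stress factors) and −0.123 (protein phosphatases 2C); with an estimated correlation none of these lists passed.

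Some control probe sets outside the comparisons carried more signal on stressed than on control arrays. For 25S ribosomal RNA the difference was 2.945 in IR20 and 1.41 in Nootripathu, for 5.8S ribosomal RNA 3.377 and 3.574, and for the 3′ ends of the poly-A spike-in transcripts 0.61 and 0.894. Probe sets for genes of the fungus Magnaporthe differed too, by 1.483 and 0.96 for an elongation factor and by 0.5035 and 0.5085 for actin. Others did not rise in both cultivars: the differences were 0.16 and −0.05 for the 5′ end of that elongation factor, 0.70 and 0.01 for Magnaporthe GAPDH, 0.21 and −0.75 for 18S ribosomal RNA and 0.38 and −0.30 for the hybridisation controls.

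The first pattern weighed was the fall of cell division genes in IR20, where the list passed, and not in Nootripathu, where the genes had a lower control level (median −1.19 against IR20, and 0.45 under stress). Loss of 5′ signal on 1 stressed IR20 array was excluded as its whole cause: without the array the lower quartile of the list's differences was 0.596, where that cause needed 0 or less. For a smaller share of dividing tissue in the stressed IR20 roots, falls of like size were taken as the prediction, with quartiles under 0.5 apart. That bound was written after the results had been seen. Theirs lay 2.75 apart, from −3.67 to −0.92. This width cannot decide, because the members differ in kind. CYCB2 (LOC4342121) ended at 3.35 and 4.23, where background limits a fall, while H2B.10 stayed at 10.2 and 10.5 under stress. The tissue explanation was left open. More than 25% of the genes rising was to exclude it, and 4.76% rose. That bound too was set after the falls had been seen, so it decides nothing. Drought could also have lowered these genes within the cells more in IR20, which the data cannot separate from such a change in tissue.

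The second was the higher 3′ spike-in signal on stressed arrays. In Nootripathu it exceeded the shift of the hybridisation controls by 1.19, against a gap between replicates of up to 0.569, which excluded hybridisation or scanning as its whole cause. In IR20 the mean excess was 0.228, so hybridisation was not excluded there, but that mean joined unlike arrays. Stressed replicate 1 had a 3′ spike-in signal of 11.09 at hybridisation controls of 10.88, and replicate 2 had 10.51 at 10.87. Replicate 2 is the array with the high 3′ to 5′ ratio, and this pair set the gap of 0.569. The IR20 value therefore does not show hybridisation to be the cause. Less poly-A RNA per unit of total RNA in stressed roots stayed open: the 3′ signal of each of the 4 spike-in transcripts was higher in both cultivars, by at least 0.468, but 18S ribosomal RNA was at −0.75 in Nootripathu. A different amount of spike-in added, or the handling of the roots, could not be told apart from it.

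The third was the 158 probe sets, 1 per gene, that differed between cultivars at least 4-fold in the same direction in control and stress, such as those of EIL1 and CPK21. If probe sequence differences between the cultivars were the cause, other probe sets of the same genes would differ the same way in about 50% of cases. They did so for 15 of 20 genes, or 75% (95% interval 50.9 to 91.3). Of those 20 genes, 10 differed at least 2-fold the same way, 4 at least 2-fold the opposite way and 4 by under 0.25, so that probe sequence and transcript level could not be told apart as causes for the set as a whole.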

How the results depend on the processing

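With 2 arrays per group, leaving out 1 array leaves its group with a lone array assumed to vary like the others; the counts then ranged from 16233 to 22335 for drought in IR20, 13116 to 21265 for drought in Nootripathu, 6509 to 14153 for the difference between the drought effects, 6415 to 14494 for the cultivars in control and 7266 to 14365 for the cultivars under stress. Past 1.5-fold, the difference between the effects moved without IR20 control replicate 2 (6948), Nootripathu control replicate 1 (6746) or 2 (6509) and Nootripathu stress replicate 1 (7362) or 2 (7241). The cultivars in control moved so without IR20 control replicate 2 (6691) and Nootripathu control replicate 1 (6524) or 2 (6415), and under stress without Nootripathu stress replicate 1 (7266) or 2 (7319). With the replicate number as a block (replicate block, replicates paired) the counts were 21878, 18490, 11251, 11080 and 12674 in the same order. A fit of only the arrays compared, with fewer residual degrees of freedom, moved the counts both ways. It gave 17253 for drought in IR20 and 7506 for the cultivars under stress, both lower than in the full fit. For drought in Nootripathu it gave 21115 and for the cultivars in control 13451, both higher. Requiring a 2-fold difference, which removes small changes by construction, left 8713, 7199, 5142, 3763 and 3587, and 4461 for the shared drought response. How far signal over background limits dim genes was not tested beyond leaving out the 40% of probe sets with the lowest signal.

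Of the lists, 0 passed with an estimated correlation in any of the 5 comparisons. With the mean over a gene's probe sets, 11 of the 11 lists of drought in IR20 still passed, 8 of 9 in Nootripathu, 9 of 10 for the difference between the effects, 6 of 8 for the cultivars in control and 7 of 8 under stress. The fry test, which asks whether a list's genes move on balance 1 way and makes no comparison with other genes, passed 30, 24, 23, 18 and 22 of 33 lists in the same order. Under spike-in scaling, chosen after the data were seen, 5 lists passed for the cultivars in control, 3 of them among the 8 that passed as deposited, and 4 under stress, each among those 8.

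Spike-in scaling also gave counts of 43988 for drought in Nootripathu, 3228 for the difference between the effects, 4710 for the cultivars in control and 4386 under stress; its construction lowers all stressed arrays relative to control arrays. Of the probe sets that passed, 55.0% were higher in IR20 as deposited and 12.2% under this scaling, and 54.8% and 3.35% in Nootripathu. It turned the sign of 28 named values that had passed as deposited, and of 4 that had not (bZIP23, NAC6 and SD1 in IR20, HSP101 between the cultivars under stress). In IR20 the 28 were EXPB10 (−0.065), CESA2 (−0.29), LAC19 (−0.027), VPE1 (−0.022), ASP1 (−0.11), RCAA1 (−0.14), CYCA1-4 (−0.093), BC1L6 (−0.20) and PP2C30 (−0.10). In Nootripathu they were TIP3-2 (−0.14), EXPA10 (−0.088), EXLA3 (−0.40), 4CLL1 (−0.46), IRO3 (−0.10), BZIP49 (−0.25), TRAB1 (−0.33), OPR7 (−0.43), 60SP0 (−0.16), RPS20 (−0.31), ASP1 (−0.087), ATG4B (−0.50), MT4A (−0.17), MT2B (−0.21), SAPK10 (−0.0085), SAPK1 (−0.15), PSAG (−0.19), P5CS1 (−0.15) and HsfA2a (−0.40). Of the 665 named results 490 stayed on the same side of the threshold under it. Beyond what the settings do by construction, the cause was not tested.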

Other observations

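Sugar transport and sucrose use moved in both directions. The sugar transporter SWEET15 rose by 3.12 ± 0.12 in IR20 and by 4.57 ± 0.12 in Nootripathu, and the sucrose synthase gene SUS4 by 4.11 ± 0.14 and 3.76 ± 0.14. SWEET1A fell by 4.56 ± 0.17 and 4.25 ± 0.17, the invertase gene CIN2 fell by 5.11 ± 0.16 in IR20 and CIN7 by 3.79 ± 0.17 in Nootripathu. Sugar transport and invertase genes rose in 10 of 26 cases and fell in 10 in IR20, and rose in 8 and fell in 9 in Nootripathu (adjusted p = 0.883 and 0.762). Low-oxygen response genes, with sucrose synthases among them, rose in 3 of 12 cases and fell in 6 in IR20, and rose in 4 and fell in 5 in Nootripathu (adjusted p = 0.364 and 0.879). The medians of the sugar list in IR20 (0.09) and of the low-oxygen list in Nootripathu (−0.21) had the opposite sign to their means (−0.19 and 0.26).

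SnRK2 kinases, which act in abscisic acid and osmotic signalling, rose in 4 of 10 cases and fell in 5 in IR20, with SAPK10 at 1.35 ± 0.10 and SAPK7 at −1.12 ± 0.13. In Nootripathu 3 rose and 2 fell; SAPK10 was at 0.89 ± 0.10 there, or −0.0085 under spike-in scaling. Metallothioneins fell in 5 of 7 cases and rose in 1 in IR20, MT-1-4B by −1.71 ± 0.18, and in Nootripathu 3 rose and 2 fell, MT-1-4B by −2.22 ± 0.18. Proteases of senescence and autophagy rose in 3 of 12 cases and fell in 2 in IR20, and rose in 2 and fell in 2 in Nootripathu, with AP25 at −3.15 ± 0.16 and −0.74 ± 0.16. None of these lists passed. Of the 4 genes in the class III peroxidase list, too few to test, 1 rose and 2 fell in IR20 and 1 rose and 3 fell in Nootripathu. Adjusted over the list alone, the counts differed for low-oxygen genes (7 falls in IR20, 5 rises and 6 falls in Nootripathu), sugar transport (9 rises in Nootripathu) and SnRK2 kinases (4 falls in Nootripathu). Under spike-in scaling the medians of the sugar and protease lists in IR20 and of the metallothioneins in Nootripathu turned from positive to negative.

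One hypothesis was tested, chosen after CPS2 and KS10 had been seen to be higher in stressed IR20 than in stressed Nootripathu roots. It held that the other genes of diterpenoid phytoalexin synthesis would be likewise, and it named 13 genes and its bounds before their values were seen. Their median, Nootripathu minus IR20 under stress, was −0.293, with quartiles of −2.01 and 0.0541. A median above −0.5 had been set beforehand to count against the hypothesis and −1 or less to count for it, so by that bound it failed. The failure was by less than the spread of the genes, and the outcome was put down as open under a rule on spread that was applied only after the value was known. Of the 13, 5 were lower in Nootripathu: CYP701A8 (−2.84 ± 0.12), CYP71Z7 (−2.57 ± 0.17), DTC1 (−2.28 ± 0.14), CYP76M5 (−2.02 ± 0.16) and CYP76M8 (−1.12 ± 0.13). CYP99A2 was higher (0.59 ± 0.13) and 7 did not pass (camera p = 0.00675, or 0.0775 with an estimated correlation).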
